A study of Caenorhabditis elegans with 4 samples.

How the data were processed

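The samples were 2 ChIP replicates and 2 inputs from L3 hermaphrodites of 1 transgenic strain grown at 20 °C, per the labels. The samples were grouped by their titles. The labels disagree in places: the description field calls the samples titled input ChIP DNA and those titled ChIP input DNA, while the titles, the source names and the sample to which each peak list is attached all go together. The genotype names the tagged gene elk-2 and the other fields name ztf-11. The gene table of the WBcel235 assembly lists these as different genes, ztf-11 (CELE_F52F12.6) on chromosome I and elk-2 (CELE_Y73B3A.5) on chromosome X. Nothing in the labels says whether the replicates came from separate cultures.

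The authors deposited peaks as a position and a q value, from the peak caller PeakSeq on the WormBase WS180 build, per the file headers and the caller's name in each line. The q value (treated as a p-value adjusted by the caller) is given in 2 fields that were checked to be equal for every peak of each list. At 343 of the peaks that overlap between the combined and replicate 2 lists, q was identical although the rank in the deposited list was not. Whether q was adjusted over a longer list of candidates is not given in the sources used here. The caller's version and q limit, the aligner, the read filters, the control used in calling and the way in which the combined list was made are not given in the sources used here. The replicate lists each belong to 1 ChIP sample. The combined list was labelled as made from both, from its name alone. Its q values, given below, mostly repeat those of replicate 2 and argue against pooled reads. Results on the combined list therefore stand close to results on replicate 2 alone. No peak list of the inputs was used here. No summit, height or read count is given, so q mixes enrichment with depth, and wide regions can reach a small q with modest enrichment. Intervals on shares cover counting error only.

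From the lists, peaks were ranked within each list by q, and −log10 q was used as the score. Strength was ranked only within a list. Across lists, q was used to count equal, smaller and larger values and to apply the limit of one list to another. Peaks were called shared when they overlapped by at least 1 bp. Shares have exact (Clopper-Pearson) 95% binomial intervals. Chance overlap came from 10000 uniform random placements of the replicate 1 peaks. Chromosome lengths of WS180 were not used here, so peaks were placed between the first and the last peak of any list on their chromosome, which is shorter than the chromosome and raises chance overlap slightly. Medians were compared with 100000 random permutations, and shares with Fisher's exact test, with Benjamini-Hochberg adjustment over the 10 tests of X shares. The planned test of chromosome shares against chromosome lengths was not made. The comparisons of X shares by strength, of spacing, of the central part of chromosomes and of the wide peaks were chosen after the data were seen. The tests of replicate overlap and of shared against unshared scores, the 1 bp rule and the rule for named regions were fixed before the data were examined. On simulated lists of 40 peaks, the placement test called 3 of 100 lists with nothing planted, and 20 of 20 with 5 planted overlaps. On the 538 replicate 2 scores, the permutation test called 5 of 100 sets with no shift and 100 of 100 with a shift of 5 in −log10 q. These simulations used fewer placements and permutations than the main tests. Their sets with nothing planted were drawn in the way the tests themselves assume. They therefore check the computation and not whether real peaks meet the assumptions.

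The rule for named regions took the 15 strongest combined peaks and the 10 strongest shared replicate 1 peaks. The replicate 1 peaks without a partner and the widest peaks were named after their values were seen. The gene table used here is of another assembly (WBcel235) and coordinates were not converted, so no peak was assigned to a gene. The planned shares of promoters and introns, the gene lists (cell type markers, pathways and gene families), the motif search and the count of peaks near ztf-11 and unc-119 were therefore not analysed here. That count was planned because the strain was taken to carry extra copies of both genes. Alternatives were another overlap rule, the stronger 50% of each list, either replicate list in place of the combined one and, added later, leaving out peaks under 100 bp or the wide stretch of chromosome I, or holding replicate 2 to the list length of replicate 1. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.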

Results

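The data map where a tagged transcription factor lay on the Caenorhabditis elegans genome in hermaphrodites at the L3 larval stage. The labels give the target as ZTF-11, a zinc finger protein, although their genotype field names elk-2, and no value here decides between them. The worms carried a transgene that adds green fluorescent protein (GFP) to the factor. Chromatin was crosslinked with 2% formaldehyde, and fragments bound by the fusion were collected with an antibody against GFP, as chromatin immunoprecipitation (ChIP) followed by sequencing. There were 4 samples: 2 ChIP replicates and 2 input samples of total genomic DNA. The 3 peak lists analysed were one for each ChIP replicate and one combined list. Each peak had a position on the WormBase WS180 build and the peak caller's own q value. A peak is called stronger here when its q is smaller. Because q also depends on depth and on peak width, this is not a direct measure of binding. The lists hold no read counts or peak heights, so the depth of each library is unknown. With 2 replicates, every p-value below describes these lists, not the spread between cultures.

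The first comparison asks how many regions each list held, how wide they were and how small their q was. The list of ChIP replicate 1 held 40 peaks, and that of ChIP replicate 2 held 538 peaks, 13.45 times as many. The combined list held 520 peaks. Replicate 1 peaks covered 33 kb in all, with a median width of 720 bp and no peak narrower than 247 bp. Replicate 2 peaks covered 240.6 kb, with a median width of 315 bp and a range from 1 bp to 10941 bp. In replicate 2, 74 peaks (13.8%) were under 100 bp wide, and 4 of them were 1 bp. In the combined list, the median width was 608 bp in the strongest 25% of peaks and 198 bp in the weakest 25%. The lists also ended at different q values. The weakest peak had q = 1.93e-06 in replicate 1, 3.37e-05 in replicate 2 and 3.3e-05 in the combined list.

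The strongest combined peak lay on chromosome X from 16929446 to 16931831 (WS180), was 2386 bp wide and had q = 8.21e-70. The same region was also the strongest in replicate 2. In replicate 1 it was split into 2 peaks, which ranked 2 and 14. The next combined peaks were X from 14525437 to 14526329 (q = 1.09e-40) and X from 6296240 to 6296790 (q = 8.59e-35). They were followed by chromosome IV from 14032490 to 14034527 (q = 1.07e-32) and chromosome II from 5543427 to 5544309 (q = 1.68e-30). The IV region was the strongest peak of replicate 1, where it had q = 2.08e-21. The peaks ranked 6 to 9 all lay on X, with starts at 2996571, 13700507, 8036130 and 4208608, and had q between 3.72e-26 and 4.33e-23. A 1758 bp peak on chromosome III from 834446 to 836203 ranked 10 (q = 3.22e-22). Of the 15 strongest combined peaks, 15 overlapped a replicate 2 peak, 11 overlapped a replicate 1 peak and 8 lay on X. The combined list has exactly the q of replicate 2 at 422 of 509 overlapping peaks. Its match with replicate 2, in these peaks and in the strongest region, is therefore not independent support. The 4 without a replicate 1 peak were X from 16056114 to 16056743, I from 1834806 to 1837468, V from 1157594 to 1158662 and I from 4172034 to 4172615.

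**Figure D1:**
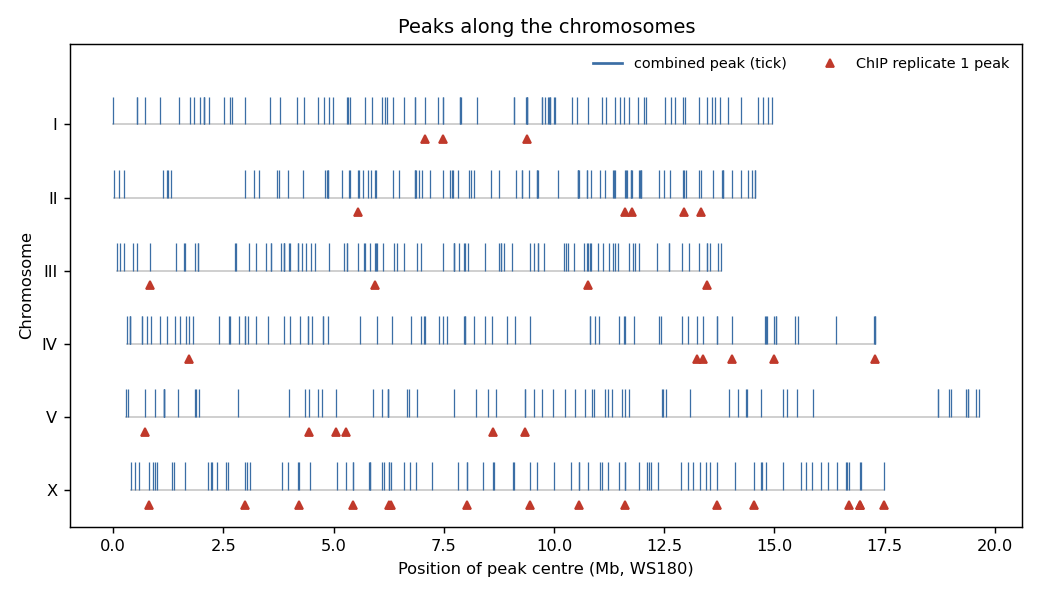
Position of each peak centre (x axis, Mb on WS180) on the 6 chromosomes (y axis), with the 520 combined peaks as blue ticks and the 40 replicate 1 peaks as red triangles; grey lines run from the first to the last peak of any list. Combined peaks lie on every chromosome, and 16 of the 40 replicate 1 peaks lie on X.

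The second comparison asks whether both ChIP replicates found the same regions. Nearly all replicate 1 regions were found again: 38 of its 40 peaks (95%, exact 95% binomial interval 83.1 to 99.4%) overlapped a replicate 2 peak by at least 1 bp. Random placement of the replicate 1 peaks on their chromosomes gave a mean of 0.27 overlapping peaks and a maximum of 3 in 10000 placements (one-sided permutation p = 0.0001, the smallest these placements can give). The reverse share was 37 of 538 replicate 2 peaks (6.88%, interval 4.89 to 9.36%). The replicate 2 list is 13.45 times as long as that of replicate 1. Against its 40 strongest peaks alone, 25 of the 40 replicate 1 peaks (62.5%) overlapped. The shared regions with the smallest replicate 1 q were IV from 14032577 to 14034494, X from 16930738 to 16931815 (q = 6.11e-20) and X from 6296313 to 6296800 (q = 3.41e-17). After these came X from 5429111 to 5429868 (q = 5.38e-15), II from 5543434 to 5544301 (q = 1.32e-14) and III from 834402 to 836244 (q = 1.14e-13). Next were X from 16681563 to 16682220 (q = 2.4e-12) and X from 8036174 to 8036822 (q = 3e-11). The list of 10 closed with I from 7474755 to 7475699 (q = 5.5e-11) and I from 7079119 to 7079891 (q = 1.07e-09). Both replicate 1 peaks without a partner lay on V. One ran from 5284005 to 5285457, ranked 11 in replicate 1 (q = 2.1e-09) and was 234 kb from the nearest replicate 2 peak. The other ran from 8620099 to 8620506, ranked 38 (q = 1.86e-06) and was 51.5 kb away. Random placement ignores where chromatin is open or reads can be mapped, so it sets a low level of chance overlap.

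Shared regions tended to have a small q in replicate 2, and they also tended to be wide. The 37 replicate 2 peaks that overlapped a replicate 1 peak had a median −log10 q of 15.1 and a median rank of 30. The other 501 had a median −log10 q of 5.44 and a median rank of 288. The median replicate 2 width was 785 bp in the shared peaks and 299 bp in the others. A wider peak overlaps more easily under the 1 bp rule and can also reach a small q. Strength and width can therefore not be separated here. The difference in medians was 9.62 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The 10 strongest replicate 2 peaks were all shared, and 28 of the 50 strongest were. The strongest replicate 2 peak without a replicate 1 partner ranked 11, and the weakest with one ranked 271. At the 38 overlaps, the median width was 720 bp in replicate 1 and 802 bp in replicate 2. Replicate 1 was the wider in 16 and replicate 2 in 22 (exact two-sided sign test, p = 0.418), so a difference in width was not shown. The 38 overlaps involve 37 replicate 2 peaks, because the strongest X region was split in replicate 1 and is counted for each part. The pairs are therefore not all independent.

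**Figure D2:**
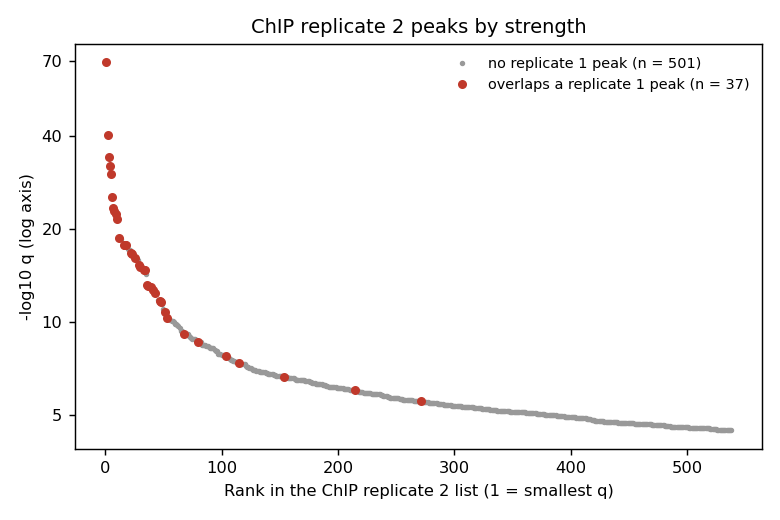
The −log10 q (y axis, log scale) of the 538 replicate 2 peaks against their rank in that list (x axis), with the 37 peaks that overlap a replicate 1 peak in red and the other 501 in grey. The red points are concentrated among the low ranks, with a median rank of 30 against 288 for the grey points.

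The third comparison sets the combined list against each replicate. It held nearly the same regions as replicate 2: 509 of the 520 combined peaks (97.9%, exact interval 96.2 to 98.9%) overlapped a replicate 2 peak, and 509 of the 538 replicate 2 peaks (94.6%, 92.4 to 96.4%) overlapped a combined peak. Only 37 combined peaks (7.12%, 5.06 to 9.67%) overlapped a replicate 1 peak. Both V peaks found in replicate 1 alone were missing from the combined list. At 422 of the 509 overlaps (82.9%) the q value was identical in both lists to every printed digit, and at 379 of these both boundaries were identical too. Among the other 87, q was smaller in the combined list at 48 and larger at 39. At the 37 combined peaks with a replicate 1 peak, 31 had exactly the q of replicate 2, 3 a smaller one and 3 a larger one. The strongest combined region, X from 16929446 to 16931831, had the same q of 8.21e-70 in both lists. The 11 combined peaks outside replicate 2 were weak, the strongest of them ranking 228 (q = 1.26e-06). The 29 replicate 2 peaks outside the combined list ranked 193 or lower (smallest q = 6.4e-07).

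The fourth comparison is the distribution over chromosomes. Combined peaks lay on all 6 chromosomes, with 88 on I, 94 on II, 97 on III, 81 on IV, 69 on V and 91 on X. Per Mb between the first and the last peak, chromosome III held most with 7.08 peaks and V fewest with 3.56, and X held 5.33. The strongest peaks were more often on X. It held 17 of the 40 strongest combined peaks (42.5%, exact interval 27 to 59.1%) against 74 of the other 480 (15.4%, 12.3 to 19%), an odds ratio of 4.06 (Fisher's exact test, two-sided p = 9.65e-05, adjusted p = 0.000483 over 10 tests of this kind). Among the strongest 25%, 33 of 130 peaks were on X (25.4%), against 58 of the other 390 (14.9%, odds ratio 1.95, Fisher's exact adjusted p = 0.013). The share did not fall steadily with strength: in the following groups of 130 peaks, from stronger to weaker, it was 13.8%, 10.8% and 20% (exact interval 13.5 to 27.9% for the weakest). The 260 stronger peaks were not shown to differ from the 260 weaker ones (19.6% against 15.4%, Fisher's exact adjusted p = 0.310). In replicate 1, 16 of 40 peaks (40%, 24.9 to 56.7%) were on X. The 40 strongest replicate 2 peaks held 17 on X, a difference that the test did not show (odds ratio 0.90, Fisher's exact p = 1). However, 25 of the 40 replicate 1 peaks overlapped one of these. The 2 groups are thus largely the same regions, and the test, which assumes separate groups, cannot decide here. Among replicate 2 peaks with no replicate 1 partner, X held 21 of the 125 strongest (16.8%) and 54 of the other 376 (14.4%), so outside the shared regions the trend was not shown (Fisher's exact adjusted p = 0.625). Leaving out the shared peaks removed 28 of the 50 strongest replicate 2 peaks, and 15 of the 37 shared peaks (40.5%) lay on X. The 125 are therefore not of the same strength as the strongest 25% of the full list. These tests treat peaks as independent, although some are neighbours.

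Peaks of the combined and replicate 2 lists were closer together than random placement gave, and in replicate 1 this was not shown. The combined list held 47 pairs of neighbouring peaks within 5 kb of each other, against a mean of 15.4 and a maximum of 28 in 1000 random placements (permutation p = 0.000999, the smallest these can give). Replicate 2, which holds nearly the same peaks, had 48 such pairs against a mean of 16.5 (permutation p = 0.000999). Replicate 1 had 1 pair against a mean of 0.142 (permutation p = 0.132). This pair was the X region that the caller split into peaks ranked 2 and 14. Split regions thus count as pairs, such as the combined peaks 200 bp apart on chromosome I, and how many pairs are of this kind was not counted. The placements also ignore uneven gene density and mappability, so the excess cannot be read as clustering of separate binding sites. Along the autosomes, 222 of 429 combined peaks (51.7%, exact interval 46.9 to 56.6%) lay in the central part of the span, from 25 to 75% of the way between the first and the last peak. A difference from the 50% of an even spread was not shown (exact binomial p = 0.499). On X the share was 45 of 91 (49.5%, 38.8 to 60.1%), and a difference between autosomes and X was not shown (Fisher's exact p = 0.730).

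The widest peaks lay together on chromosome I. The 3 widest of the combined list ran from 9905119 to 9916059 (10941 bp, q = 1.68e-13), from 9882671 to 9890522 (7852 bp, q = 6.26e-11) and from 9916260 to 9919736 (3477 bp, q = 3.63e-06). They were the only combined peaks in a stretch of 37.1 kb, of which they covered 60.1%. They made up 9.39% of all bases in the combined list, whose other peaks had a median width of 316 bp. Replicate 2 also held 3 peaks in this stretch. Replicate 1 held 0 peaks there or within 50 kb of it. The next widest combined peak was 3234 bp, on III from 13778044 to 13781277 (q = 8.85e-06).

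**Figure D3:**
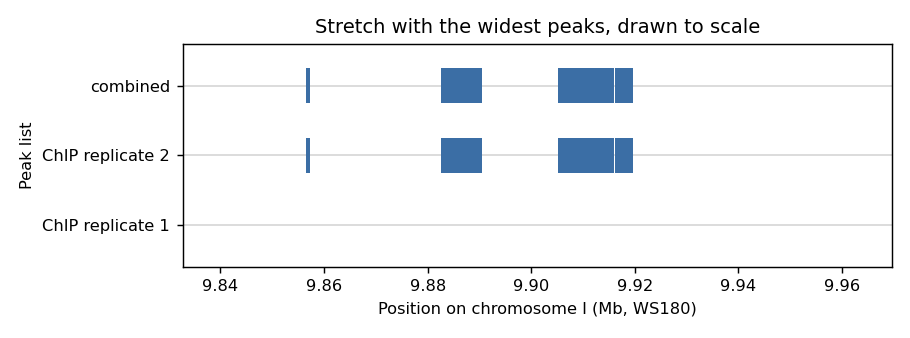
Peaks drawn to scale (blue boxes) along chromosome I (x axis, Mb on WS180) in the 37.1 kb stretch with the 3 widest combined peaks and 50 kb to either side, for the combined list and each replicate (y axis). The 3 wide peaks appear in the combined and replicate 2 lists, and replicate 1 has 0 peaks in the window.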

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

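Alternatives that left out peaks under 100 bp or the wide stretch, matched list lengths, or bear on X strength and central position were chosen after the data were seen. Of 35 alternatives, 31 kept their direction and their side of the threshold or stayed within the interval. Many of them could hardly differ, so this count is a weak measure of robustness. The 50% overlap rule gave the same values as the 1 bp rule. Settings without replicate 1 used the replicate 2 list, which overlapped 97.9% of the combined peaks. Those without replicate 2, with 40 peaks at most, were each moved, weaker or reversed. The share of replicate 1 peaks found in replicate 2 was between 62.5% (replicate 2 held to its 40 strongest peaks) and 95%, each at the smallest p the placements give. The share of peaks on X was 17.5% in the combined list and ranged from 16.7% without replicate 1 to 40% without replicate 2. The odds ratio of X in the strongest 25% of peaks, 1.95 in the combined list, was 2.93 in the stronger 50% of the list, 2.26 without peaks under 100 bp and 1.99 without replicate 1, and past the threshold in each. It was 1.73 without replicate 2, where it lost significance with 40 peaks. It was 1.20 and not significant among replicate 2 peaks outside replicate 1, which lack 28 of the 50 strongest replicate 2 peaks. The cause was not tested. The central share of autosomal peaks was 53.6% without replicate 1 and turned to 33.3% without replicate 2, where 24 peaks remained. No share of all autosomal peaks passed the threshold in any of these settings. On single chromosomes, 0 of 6 replicate 1 peaks on IV were central (exact binomial p = 0.031, not adjusted), and no other chromosome passed in any list. The settings that needed the position of ztf-11 and unc-119, an annotation or a sequence of WS180 were not run. No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, have no peak list used here. Read depth is unknown, so peaks seen in 1 replicate alone cannot be called absent from the other.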

Other observations

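The tests in this part were chosen after the results they bear on were seen, except the overlap of the replicates and the score difference between shared and unshared peaks, which were fixed beforehand but read here against explanations chosen later. Long intervals without any peak stood on 2 chromosomes. On V, no combined peak lay from 15874114 to 18711923 (WS180), an interval of 2.84 Mb, where random placement of the 69 peaks gave a median longest interval of 1.26 Mb (permutation p = 0.0007, adjusted p = 0.0027 over 6 chromosomes). On II, none lay from 1320720 to 2994914, an interval of 1.67 Mb against a median of 0.75 Mb (permutation p = 0.0009, adjusted p = 0.0027). The same intervals were empty in replicate 2, which holds nearly the same peaks and so gives no independent support. The longest intervals on I, III, IV and X did not pass the test, with adjusted permutation p from 0.186 on IV to 0.878 on X. The placements treat peaks as independent and evenly spread, although the combined list held 47 pairs within 5 kb against a mean of 15.4 in such placements. Close pairs, split regions and uneven gene density can each lengthen the empty intervals. These p-values therefore show a departure from even placement and not that the intervals themselves are unusual. Read mappability in these intervals was not tested.

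The combined list repeats the q of replicate 2 at 422 of 509 overlapping peaks (82.9%). Pooled ChIP reads of both replicates would add reads, and so change q, most of all where replicate 1 has its own peaks. At 83.8% of those 37 peaks (exact interval 68.0 to 93.8%) q was exactly that of replicate 2, which argues against pooling. A candidate explanation is that replicate 2 reads were called a second time: at 379 of the 379 peaks with the same boundaries, q was also the same. These peaks were picked for being unmoved, so their equal q largely restates the match. A second calling leaves open why boundaries moved at the other 130 (larger shift per peak, median 11 bp, at most 455 bp). It also leaves open why 87 of these had another q (48 smaller and 39 larger, by up to 2.16 in −log10 q). Nor does it say why 11 peaks were in the combined list alone and 29 in replicate 2 alone. No biological explanation was tested.

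The replicate 1 list is 13.45 times shorter than that of replicate 2. A stricter q limit in replicate 1 is argued against as the whole cause, since 244 replicate 2 peaks pass the largest q of replicate 1. Lower sensitivity in replicate 1 stays open. The shared peaks were the stronger ones of replicate 2 by 9.62 in median −log10 q, and they were also the wider ones by median width. A stricter limit, or regions that many pull-downs recover, would also give this, so the difference cannot single out lower sensitivity. Of the 50 strongest replicate 2 peaks, 28 were shared. Lower sensitivity alone would not give the replicate 1 peak on V that ranked 11 (q = 2.1e-09) and had no replicate 2 partner. Shallower sequencing and weaker enrichment would both lower sensitivity, and without read counts neither was tested, nor was a biological difference between the worms. Material from another target or sample stays open too: 95% of replicate 1 peaks were found in replicate 2, but regions that many pull-downs recover would also be shared, and the overlap between different targets was not measured.

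The 3 widest peaks stand in one 37.1 kb stretch of chromosome I. They were singled out after they were seen to lie together, and only 200 bp separates the pair on the right, so chance position was not tested. Extra copies of the ztf-11 region in the transgene might raise reads over the whole inserted segment. The gene ztf-11 is on chromosome I (elk-2, the gene in the genotype label, is on X). However, the WS180 position of ztf-11 was not used here. The inputs came from the same strain, and the control used in calling is not given. Extra copies and broad binding at the locus can therefore not be told apart. The lack of a replicate 1 peak in the stretch does not decide between them. Only 28 of the 50 strongest replicate 2 peaks were shared with replicate 1.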
